A study of Mus musculus with 9 samples.

How the data were processed

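RNA was extracted from cultured 66cl4 cells kept under puromycin after transduction with a hairpin vector, and libraries were made with the NuGEN Universal Plus mRNA-Seq kit, per the labels' protocols. FastQC, MultiQC, STAR and the genome build mm10 are named in the submitters' processing notes, without versions. The counting tool, its annotation and its strand setting are not given in the sources used here. The deposited table holds raw read counts per gene symbol for 55418 symbols in 9 libraries, with whole numbers in every column, and these counts were used as deposited. Every symbol matched GENCODE M21, the annotation of mm10 used for coordinates, in which 115 symbols belong to more than 1 gene.

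Groups and replicate numbers were taken from the sample titles, and each of the 9 columns matched 1 title. Library totals ranged from 27758862 to 52691960 counts, which sets the precision of low values: a gene without counts in a group was read as at or below a floor of 3 counts over the group, and genes with 1 to 3 counts are given as a ratio with a 95% counting interval. Intervals and floors cover counting error only, since the reads carried no stated molecular identifiers. Replicate pairs of a group differed by more than sampling noise (chi-square per degree of freedom 9.24 to 45.2 over genes with at least 20 reads in the pair), so no library was counted as a repeat of another. The transcripts of the mitochondrial genome took 1.39% to 2.47% of counts, and the most abundant gene, Eef1a1, took 1.21% to 1.61%.

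Counts were analysed in R 4.3.3 with edgeR 4.0.16. Genes were kept by filterByExpr, which left 15914, libraries were scaled with TMM factors, and all 9 libraries entered a single quasi-likelihood fit with the group as the only term and robust estimation. The comparisons were shEya3_KD1 against SCR, shEya3_KD2 against SCR and shEya3_KD2 against shEya3_KD1, at a Benjamini-Hochberg adjusted p of 0.05. Standard errors of log2 fold changes were derived from the fitted fold change and its F statistic. With 3 libraries against 3, an exact permutation test of a single value cannot go below 0.1, so p-values rest on the model across genes. In simulated counts with known changes the fit recovered 78.8% of genes changed 1.5-fold in shEya3_KD1 against SCR, 89.6% in shEya3_KD2 against SCR and 85.7% between the hairpins. It recovered at least 99.2% of those changed 2-fold. Of the calls 7.54%, 8.10% and 4.30% were unchanged genes. Few genes were changed in the simulation, with 199, 210 and 395 calls among 15397 genes. In the data 50.3%, 45.3% and 49.6% of genes tested were called, so these rates may not carry over.

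There were 25 gene lists, written down before the data were examined, as were the design, the alternatives and the rule for named genes. They covered the Eya-Six-Dach family, NF-kB targets, chemokines, cytokines and growth factors of myeloid cells, interferon-induced genes, class I antigen presentation, ligands of NK cell receptors and immune checkpoints, Myc targets, cell cycle, p53 targets, DNA damage and repair, epithelial and mesenchymal genes, collagens and matrix, hypoxia and glycolysis, cholesterol synthesis, the unfolded protein and amino acid stress response, immediate early genes and Nrf2 targets. Markers of macrophages, lymphocytes, fibroblasts and endothelial cells were included for other cell types, and mitochondrially encoded genes and replication-dependent histones for RNA quality. Lists could share members: Ccl2 and Cxcl1 were in the NF-kB and chemokine lists, and Irf1 and Cxcl10 in the NF-kB and interferon lists. Counts and calls of such lists are therefore not independent. List members were counted by their own test, adjusted over all genes tested and adjusted over the list alone. Lists were compared with all other genes by camera (limma 3.58.1, preset correlation 0.01, and again with an estimated correlation), and fry tested whether the members of a list moved on balance one way or in either direction.

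The rule named Eya3, the measured Eya-Six family genes, Myc and Cd274, the 12 rising and 12 falling genes with the largest smaller change over both hairpins, 6 and 6 per hairpin and 8 and 8 between hairpins by fold change. These needed 1 CPM in a compared group and no overlap between the libraries of the groups, and predicted genes and pseudogenes were passed over. Up to 4 members of each list were added, which gave 148 genes, of which the text describes a part. Of these 22 overlap another tested gene in the annotation, 10 of them on the same strand, and reads in such overlaps, or between near-identical paralogs such as Raet1d and Raet1e, may be split between genes.

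Alternatives were RLE size factors, DESeq2 1.42.0, limma-voom, no filter, a filter of 5 CPM in 3 libraries, only the groups compared, the replicate number as a block, a minimum fold of 1.5 (glmTreat) and each library left out in turn. Thinning of all libraries to the shallowest was chosen after the data had been seen. In 20 simulations of a list shifted 1.3-fold camera called it in 20, with 1 false call among the other lists in that comparison and 1 in the comparison where no list was shifted. Those simulations drew each gene independently, so they do not cover false calls of lists whose members move together. In the data the interferon-induced list had an estimated correlation of 0.76. Such a correlation was estimated from all 9 libraries and so was the same in each comparison. A scan for neighbouring genes that shift together used medians over 41 genes in chromosome order, for genes with a mean of at least 4 CPM, against the bound that 95% of 200 permuted gene orders kept to. In simulated values with a block of 100 genes lowered, 99 lay in called windows and 0 windows were called elsewhere.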

Results

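Messenger RNA was counted in 9 cultures of 66cl4, a mouse line of triple negative mammary carcinoma (a breast tumour type without hormone receptors or Her2 amplification). The cells carried either a scrambled short hairpin RNA (SCR) or 1 of 2 hairpins named for Eya3 (shEya3_KD1 and shEya3_KD2), with 3 libraries from biological replicates in each of the 3 groups. A short hairpin RNA is processed by the cell into a small RNA that lowers the messenger RNA it matches. Library totals lay between 27758862 counts (shEya3_KD2 replicate 2) and 52691960 counts (shEya3_KD2 replicate 1), and 15914 genes were tested. The groups lay apart in a principal component analysis: the first component, 62.3% of the variance, set shEya3_KD1 against the other libraries, and the second, 25.9%, set shEya3_KD2 against SCR. The labels name biological replicates without describing the separate cultures, so p-values cover the spread between these libraries.

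The first question was whether Eya3, a transcriptional co-activator with a phosphatase domain, was lowered by each hairpin. Eya3 (mm10, chromosome 4, 132638987 to 132724765) stood at 72.9 ± 5.56 CPM (counts-per-million, mean ± SD, n = 3) in SCR. It was at 23.1 ± 1.71 CPM in shEya3_KD1, 31.7% of the SCR mean, and at 37.5 ± 3.02 CPM in shEya3_KD2, 51.5% of the SCR mean. Each of the 3 libraries of either hairpin lay below each SCR library. The log2 fold changes were -1.66 ± 0.08 (SE) and -0.96 ± 0.08, with adjusted p of 3.48e-10 and 3.27e-07 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, and Eya3 was 0.70 ± 0.08 higher on the log2 scale in shEya3_KD2 than in shEya3_KD1. Eya1, a paralog of Eya3, fell with both hairpins, from 46.9 ± 1.76 CPM to 25.6 ± 2.83 and 29.4 ± 1.15 CPM. Eya2 rose from 0.135 ± 0.0492 CPM to 0.950 ± 0.300 and 0.464 ± 0.0343 CPM. Six3, a homeobox transcription factor, rose with both (log2 fold changes 0.87 ± 0.10 and 0.65 ± 0.10), and Dach1 fell from 3.33 ± 0.714 CPM to 0.209 ± 0.0583 CPM with shEya3_KD1 and had 1 count in shEya3_KD2 against 469 in SCR, a ratio of 396 (95% counting interval 70.7 to 15674). Of the 9 measured members of the Eya-Six-Dach family list, 3 rose and 5 fell with shEya3_KD1, and 4 rose and 4 fell with shEya3_KD2, where the median was 0.14 (0.026 to 0.21 with each library left out in turn) and the mean -0.997 (the same counts adjusted over the list alone).

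**Figure D1:**
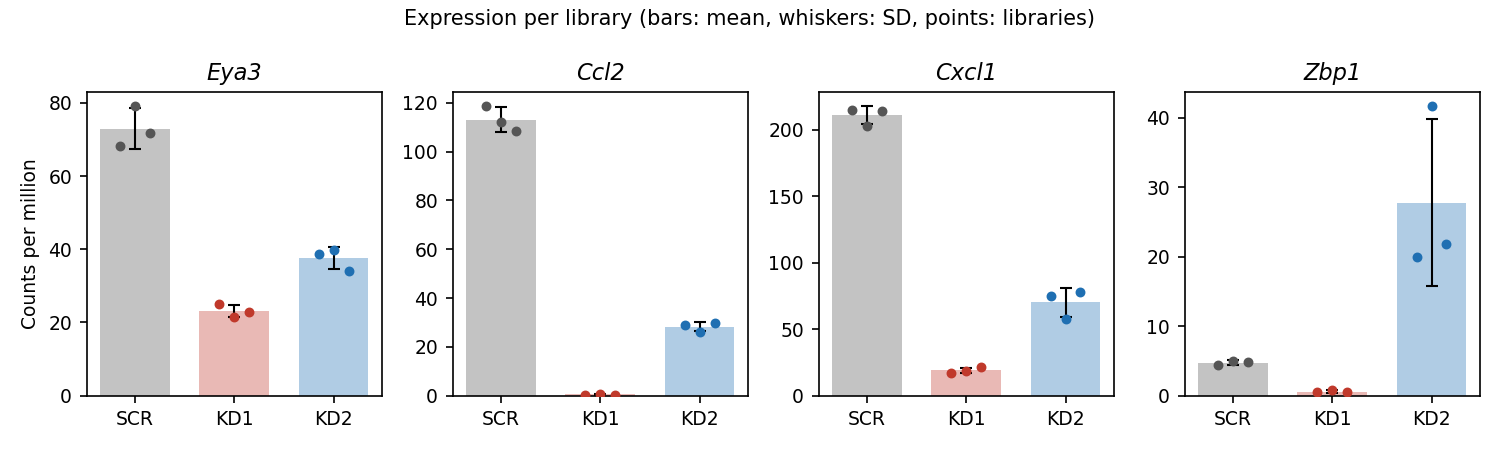
Levels (CPM) of Eya3, Ccl2, Cxcl1 and Zbp1 in each library of SCR, shEya3_KD1 (KD1) and shEya3_KD2 (KD2). Bars show means, whiskers SD and points the 3 libraries. Eya3 was lower with both hairpins, while Zbp1 was 4.76 CPM in SCR, 0.596 CPM in shEya3_KD1 and 27.8 CPM in shEya3_KD2.

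The comparison of shEya3_KD1 with SCR asked what changed with the hairpin that left less Eya3. Ccl2, a chemokine that attracts monocytes (mm10, chromosome 11, 82035571 to 82037453), went from 113 ± 5.06 CPM to 0.493 ± 0.163 CPM (log2 fold change -7.81 ± 0.13, adjusted p = 2.72e-15 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, lower in 3 of 3 libraries). Cxcl1, a chemokine that attracts neutrophils, went from 211 ± 6.75 to 18.9 ± 2.09 CPM, and Ccl7 from 6.09 ± 0.277 to 0.0328 ± 0.0383 CPM. Ccl4 had no counts in the 3 shEya3_KD1 libraries against 27 in SCR, at least 7.40-fold lower by a floor of 3 counts over the group. Mmp9, a matrix protease, fell by 4.87 and Traf1, a signalling adaptor downstream of TNF receptors, by 3.93 on the log2 scale. Of 27 measured NF-kB target genes 22 fell and 1 rose (23 and 1 adjusted over the list alone; 0 to 1 rose with each library left out), with a median log2 fold change of -1.03. Of 14 measured chemokines 11 fell and 2 rose, with a median of -2.88, or -2.69 with Ccl4 at its bound. Adjusted over the list alone the counts were 11 and 2, and 1 to 2 rose with each library left out. Ccl2 and Cxcl1 were counted in both lists.

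Of 44 measured interferon-induced genes 38 fell and 1 rose with shEya3_KD1 (the same numbers adjusted over the list alone; 0 to 1 rose with each library left out), with a median log2 fold change of -1.34. As a group they passed limma's camera at its preset correlation but had an adjusted p = 0.576 with an estimated correlation. That correlation also took in the spread among the shEya3_KD2 libraries, which are not part of this comparison. Zbp1, a sensor of Z-form nucleic acids, went from 4.76 ± 0.303 to 0.596 ± 0.174 CPM, and the antiviral GTPase Mx2 from 2.10 ± 0.327 to 0.802 ± 0.110 CPM. Among 20 measured genes of class I antigen presentation 18 fell and 1 rose (also when adjusted over the list alone), with a median of -0.82. Tapbp, which helps peptides load onto class I molecules, went from 213 ± 9.11 to 76.6 ± 8.68 CPM, and Tap1, a subunit of the peptide transporter, from 7.94 ± 0.773 to 3.26 ± 0.340 CPM. Of 18 measured ligands of NK cell receptors and immune checkpoints 12 fell and 2 rose (13 and 2 adjusted over the list alone; 1 to 2 rose with each library left out), with a median of -0.85. Raet1e, a ligand of the receptor NKG2D, fell by 1.77 on the log2 scale. Clec2d, a ligand of another NK cell receptor, went from 2.39 ± 0.146 to 0.121 ± 0.0444 CPM (log2 fold change -4.29 ± 0.32). The reading of Raet1e is uncertain because it shares its span with Raet1d and H60b. Cd274, which encodes the checkpoint ligand PD-L1, was at 4.74 ± 0.301 CPM against 4.79 ± 0.302 CPM in SCR and did not pass the test. Markers of macrophages, fibroblasts and lymphocytes, which could mark other cells in the cultures, had medians of -1.46, -1.14 and -0.94 (lymphocytes -1.10 to -0.52 with each library left out) over 7, 6 and 4 measured genes. Of 17 macrophage markers 10 were too low to test, among them Tyrobp, C1qa and C1qc with no counts in SCR. Lyz2 and Cd14 stood at 38.6 and 27.7 CPM in SCR, so the median does not show a loss of macrophages. Endothelial markers went the other way, with a median of 0.72, 3 of 5 risen and 2 fallen. Of the lymphocyte markers 1 rose and 1 fell, and no group mean was above 1.01 CPM (Cd3g in shEya3_KD1).

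Other groups moved less, or both ways, with shEya3_KD1. Among 27 measured Nrf2 targets, genes of antioxidant defence, 17 fell and 5 rose (the same numbers adjusted over the list alone; 2 to 6 rose with each library left out), with a median log2 fold change of -0.34. Slc7a11, the cystine importer, went from 66.9 ± 9.26 to 29.0 ± 3.65 CPM, and Osgin1 from 25.9 ± 4.24 to 1.99 ± 0.624 CPM. Of 31 hypoxia and glycolysis genes 16 rose and 5 fell (the same numbers adjusted over the list alone; 3 to 6 fell with each library left out), with a median of 0.28. Car9, a carbonic anhydrase of hypoxic cells, went from 14.6 ± 3.35 to 107 ± 13.5 CPM and Pdk1 from 29.9 ± 2.96 to 74.7 ± 2.75 CPM, whereas Egln3, an oxygen-sensing hydroxylase that is also induced by hypoxia, fell by 1.99 on the log2 scale. Of 15 measured cytokines and growth factors of myeloid cells 10 fell and 3 rose (the same numbers adjusted over the list alone); Csf3 fell by 3.29 on the log2 scale, while Spp1, the secreted phosphoprotein osteopontin, went from 289 ± 6.96 to 1856 ± 59.7 CPM. Of 28 immediate early genes 10 rose and 12 fell (10 and 13 adjusted over the list alone), with a median of -0.18 and a mean of 0.10. Klf2 was at 1.33 ± 0.262 CPM in SCR and at 14.4 ± 1.95 CPM in shEya3_KD1, and Ier3 at 304 ± 12.8 and 52.0 ± 3.83 CPM. Of 18 measured epithelial genes 6 rose and 8 fell (7 and 9 adjusted over the list alone), with a median of -0.05 (-0.46 to 0.087 with each library left out) and a mean of 0.33; Grhl2, a transcription factor of epithelial cells, went from 61.4 ± 1.95 to 1.33 ± 0.158 CPM.

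The genes with the widest changes in shEya3_KD1 were switched nearly on or off. Spint2, an inhibitor of membrane serine proteases (mm10, chromosome 7, 29256323 to 29281912), had 5 counts in the 3 SCR libraries and 6229 in shEya3_KD1 (log2 fold change 10.45 ± 0.21). Trp63, a transcription factor of basal epithelia, had 1 count in SCR and 567 in shEya3_KD1, a ratio of 690 (95% counting interval 123 to 27303). Pid1, Pnma2, Etfbkmt and Hey2 had no counts in SCR and were at least 142-fold, 109-fold, 91.3-fold and 68.2-fold higher. Procr, the endothelial protein C receptor, went from 164 ± 5.99 to 0.0611 ± 0.0220 CPM. Tysnd1, Gypc, Dnah7a, Efhc2 and Rxfp1 had no counts in shEya3_KD1 and were at least 556-fold, 426-fold, 315-fold, 192-fold and 153-fold lower. In all, 3839 genes rose and 4172 fell with shEya3_KD1, 50.3% of those tested, and of these 823 rose and 1517 fell more than 2-fold. By limma's camera with a preset correlation of 0.01, 7 of the 25 lists passed the threshold: interferon-induced genes (adjusted p = 1.78e-10), NF-kB targets (8.21e-10), class I antigen presentation (1.92e-06), chemokines (1.00e-04), ligands of NK cell receptors and immune checkpoints (0.00233), Nrf2 targets (0.00621) and hypoxia and glycolysis (0.0297). In the same order these were adjusted p = 0.576, 0.126, 0.329, 0.0936, 0.148, 0.620 and 0.629 with an estimated correlation, so each of the 7 calls was lost; with that correlation 3 lists had an unadjusted p past the threshold in camera, and limma's fry called 16 lists by direction and 25 in either direction. The hypoxia call was also lost without SCR replicate 1 and without shEya3_KD1 replicate 1.

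The comparison of shEya3_KD2 with SCR asked the same of the hairpin that left more Eya3. All 44 measured interferon-induced genes rose (also adjusted over the list alone), with a median log2 fold change of 1.81. As a group they passed limma's camera at its preset correlation but had an adjusted p = 0.580 with an estimated correlation. Zbp1 had a log2 fold change of 2.53 ± 0.28, Mx2 reached 21.4 ± 7.52 CPM and Mx1 8.02 ± 2.92 CPM, against 2.10 ± 0.327 and 0.890 ± 0.0883 CPM in SCR. The adjusted p of Mx1 was 4.87e-07 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, with the gene higher in 3 of 3 libraries. The libraries differed in size of response: the median log2 difference of the 44 genes from the SCR mean was 1.49 in replicate 1, 2.19 in replicate 2 and 1.55 in replicate 3. Among class I antigen presentation genes 12 of 20 rose and 1 fell (the same numbers adjusted over the list alone), with a median of 0.28. Tap1 went from 7.94 ± 0.773 to 27.9 ± 8.06 CPM and Tapbp from 213 ± 9.11 to 296 ± 44.4 CPM. Cd274 rose from 4.79 ± 0.302 to 9.39 ± 2.55 CPM.

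Of 30 measured genes of the unfolded protein and amino acid stress response 18 rose and 3 fell with shEya3_KD2 (the same numbers adjusted over the list alone), with a median log2 fold change of 0.25. Chac1, an enzyme that degrades glutathione, went from 60.1 ± 9.55 to 103 ± 5.20 CPM and Sesn2, a stress-induced sestrin, rose by 1.16 ± 0.07 on the log2 scale. Of 27 Nrf2 targets 16 rose and 5 fell (16 and 6 adjusted over the list alone; 3 to 5 fell with each library left out), with a median of 0.45; Slc7a11 reached 160 ± 14.9 CPM and Gsta4, a glutathione transferase, went from 61.6 ± 5.63 to 115 ± 19.6 CPM, while Osgin1 fell from 25.9 ± 4.24 to 11.2 ± 2.18 CPM. By limma's camera both lists had an adjusted p = 0.608 with an estimated correlation. Chemokines and NF-kB targets went both ways, with 6 of 14 fallen and 4 risen (7 and 4 adjusted over the list alone) and 13 of 27 fallen and 6 risen (14 and 6 adjusted over the list alone). Ccl2 fell to 28.2 ± 1.88 CPM and Cxcl1 to 70.1 ± 11.0 CPM. Markers of macrophages, fibroblasts and lymphocytes had medians of -1.28, -0.84 (-0.90 to -0.47 with each library left out) and -0.56, and endothelial markers -0.90. Myc, which encodes a growth-promoting transcription factor, rose from 189 ± 3.09 to 269 ± 11.1 CPM with shEya3_KD2 and did not pass the test with shEya3_KD1 (log2 fold change 0.09 ± 0.07).

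Among the widest changes with shEya3_KD2, Sstr5, a somatostatin receptor, went from 0.0833 ± 0.0314 to 12.3 ± 0.266 CPM. Irx1 had 2 counts in SCR and 536 in shEya3_KD2 (ratio 317, 95% counting interval 87.4 to 2628). Brinp3 fell from 12.5 ± 0.508 to 0.0855 ± 0.0527 CPM and Pcdh9, a protocadherin, from 7.23 ± 0.393 to 0.0274 ± 0.0294 CPM. Cd36, a fatty acid transporter, had no counts in shEya3_KD2 and was at least 46.4-fold lower. In all 3656 genes rose and 3554 fell, 45.3% of those tested, and of these 536 rose and 944 fell more than 2-fold. Camera called 4 of the 25 lists: interferon-induced genes (adjusted p = 3.18e-22), the unfolded protein and amino acid stress response (0.00132), Nrf2 targets (0.00349) and class I antigen presentation (0.0246). In the same order these were adjusted p = 0.580, 0.608, 0.608 and 0.608 with an estimated correlation, so each of the 4 calls was lost; with that correlation 0 lists had an unadjusted p past the threshold in camera, and fry called 16 by direction and 24 in either direction.

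**Figure D2:**
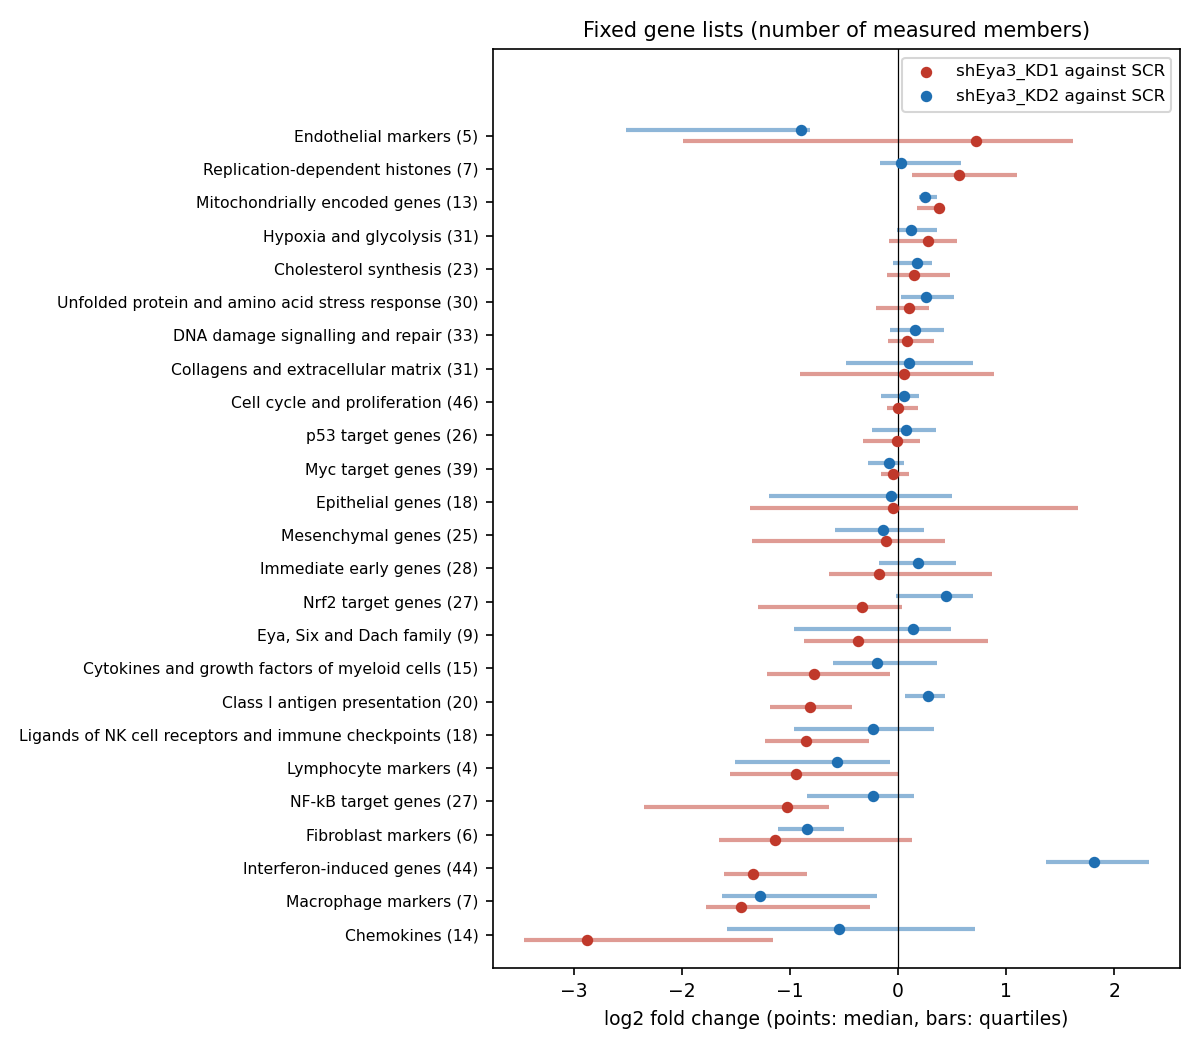
Median log2 fold change against SCR (points) and quartiles (bars) of the measured members of each fixed gene list, for shEya3_KD1 and shEya3_KD2, with the number of measured members in brackets. Interferon-induced genes lay at -1.34 with shEya3_KD1 and at 1.81 with shEya3_KD2.

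A change seen with both hairpins depends less on unintended targets of either, so calls in the same direction were counted. Thbs1, an adhesive matrix glycoprotein (mm10, chromosome 2, 118111876 to 118127133), rose from 19.3 ± 2.71 CPM to 383 ± 57.0 CPM with shEya3_KD1 and to 135 ± 29.9 CPM with shEya3_KD2. Mrc2, a collagen receptor, rose from 1.12 ± 0.194 to 78.6 ± 11.2 and 20.5 ± 3.80 CPM. Aqp1, a water channel, went from 0.124 ± 0.0467 to 16.9 ± 1.57 and 6.08 ± 1.16 CPM, and Notch1, a receptor of cell-contact signalling, from 0.510 ± 0.0970 to 7.19 ± 0.966 and 10.0 ± 3.90 CPM. Spns2, an exporter of sphingosine 1-phosphate, rose by 3.00 and 2.98 on the log2 scale, Ptgds by 3.60 and 3.44, Bgn by 3.42 and 3.28, and Nudt14 by 6.58 and 6.33. Among genes that fell with both, Adam22 went from 17.6 ± 1.25 to 0.130 ± 0.0399 and 0.403 ± 0.0410 CPM, Pnma5 from 16.7 ± 1.06 to 0.240 ± 0.0778 and 0.612 ± 0.208 CPM, and Slc7a14 from 8.62 ± 0.371 to 0.132 ± 0.0734 and 0.193 ± 0.129 CPM. Mmp1b and the myogenic factor Myf5 had no counts with either hairpin. Myf5 and Mmp1b were at least 67.9-fold and 49.3-fold lower in shEya3_KD1 and 69.8-fold and 50.7-fold lower in shEya3_KD2. Cps1 fell by 4.94 and 3.86 on the log2 scale, and Erbb4, a receptor tyrosine kinase, had log2 fold changes of -4.65 ± 0.38 and -3.91 ± 0.34. Odc1, the first enzyme of polyamine synthesis, fell from 2754 ± 107 to 722 ± 29.4 and 1315 ± 73.4 CPM, and podoplanin (Pdpn) from 368 ± 14.3 to 59.6 ± 3.64 and 162 ± 20.5 CPM. Among all 15914 genes tested 1637 rose and 2115 fell with both hairpins. Of the fixed lists, 27 measured NF-kB targets had 12 members that fell with both, 1 that rose and 4 that went opposite ways. The 31 measured hypoxia and glycolysis genes had 10 that rose with both and 2 that fell. Cholesterol synthesis genes had 9 that rose with both and 3 that fell, among them Insig1, which went from 109 ± 2.39 to 234 ± 7.91 and 162 ± 4.94 CPM.

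In total 1637 genes rose with both hairpins and 2115 fell with both, 3752 in the same direction, and 841 were called in opposite directions. Independent lists of these sizes would share 882 rising and 932 falling genes and 1816 in opposite directions. In 20 simulations of unchanged groups against the same SCR libraries the mean number called in both was 0.1. Across genes, which are not independent replicates, the log2 fold changes had a correlation of 0.441 against 0.470 in the simulations, a share of 65.9% with the same sign against 66.2%, and a covariance of 0.436 against 0.0155. The simulated groups differed only by noise between libraries, so they give no baseline for cultures that had drifted apart. Part or all of the excess may come from the shared SCR libraries, which are too few to be split.

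**Figure D3:**
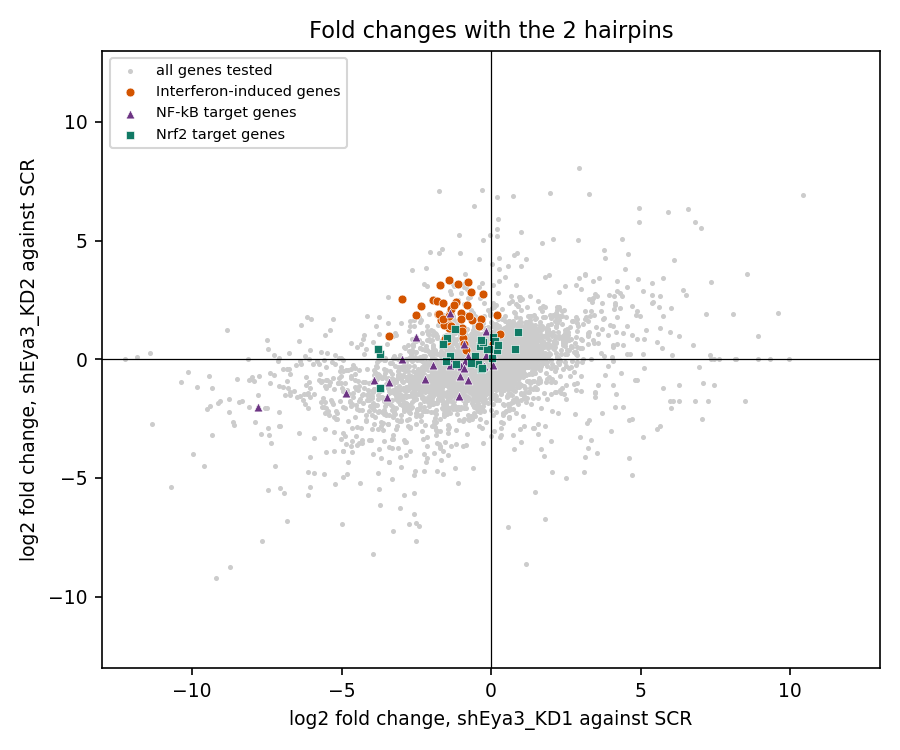
Log2 fold change against SCR with shEya3_KD1 (horizontal axis) and shEya3_KD2 (vertical axis) of the 15914 genes tested (grey), with members of the interferon, NF-kB and Nrf2 lists marked. Of the 44 interferon-induced genes 38 fell with shEya3_KD1 and rose with shEya3_KD2.

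The direct comparison of shEya3_KD2 with shEya3_KD1 tested whether the effects of the hairpins differed, with the SCR libraries cancelled out. All 44 measured interferon-induced genes were higher in shEya3_KD2 (also adjusted over the list alone), with a median log2 difference of 3.15. Zbp1 was 5.50 ± 0.38 higher on the log2 scale, with an adjusted p of 1.97e-06 in edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment and higher in 3 of 3 libraries. NF-kB targets (22 of 27 higher and 1 lower, median 1.15), chemokines (10 of 14 higher and 2 lower, median 2.17), class I antigen presentation genes (17 of 20 higher and 1 lower, median 1.03) and Nrf2 targets (23 of 27 higher and 1 lower, 1 to 2 lower with each library left out, median 0.70) were likewise mostly higher in shEya3_KD2, with these same numbers adjusted over each list alone. Slc7a11 differed by 2.47 ± 0.12 and Grhl2 by 3.45 ± 0.10. Gypc, Tysnd1 and Dnah7a, which had no counts in shEya3_KD1, stood at 11.7 ± 0.293, 14.1 ± 1.11 and 9.60 ± 1.05 CPM in shEya3_KD2, at least 459-fold, 562-fold and 384-fold higher. In the other direction Cldn1, a tight junction protein, had 419 counts in shEya3_KD1 and none in shEya3_KD2 (at least 144-fold lower), and Emcn had 264 counts and none (at least 90.4-fold lower). Klf2 was 2.77 ± 0.14 and Spp1 2.12 ± 0.07 lower in shEya3_KD2 on the log2 scale. In all 4301 genes were higher and 3588 lower in shEya3_KD2, 49.6% of those tested.

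By camera 5 of the 25 lists differed between the hairpins: interferon-induced genes (adjusted p = 1.39e-24), NF-kB targets (1.18e-09), Nrf2 targets (3.79e-08), class I antigen presentation (4.45e-08) and chemokines (6.05e-04). In the same order these were adjusted p = 0.362, 0.131, 0.350, 0.350 and 0.131 with an estimated correlation, so each of the 5 calls was lost; with that correlation 3 lists had an unadjusted p past the threshold in camera, and fry called 14 by direction and 25 in either direction.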

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

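The counts of other label splits, the order by Eya3 level and the macrophage markers were tests chosen only after the result was seen, and the thinning of libraries was also added after seeing the data.

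Genes are listed here because they moved one way with shEya3_KD1 and the other way with shEya3_KD2. Both calls were kept with RLE size factors, DESeq2, the replicate number as a block and each library left out in turn. The difference between hairpins also passed edgeR's quasi-likelihood test. The other alternatives, among them the minimum fold (glmTreat), were not part of this rule. Of 26 named genes called in opposite directions 21 met the rule. By camera at its preset correlation 3 lists also went opposite ways, with median log2 differences (shEya3_KD2 minus shEya3_KD1) of 3.15 for interferon-induced genes, 1.03 for class I antigen presentation and 0.70 for Nrf2 targets. None of these list calls was kept by camera under the alternative correlation: between hairpins they had adjusted p = 0.362, 0.350 and 0.350 with an estimated correlation. Higher in shEya3_KD2 on the log2 scale were Zbp1 (5.50), Clec2d (5.16), Mx1 (4.84), Mx2 (4.72), Gbp5 (4.60), Tap1 (3.09), Slc7a11 (2.47), Gsta4 (2.39), Tapbp (1.95), Plk2 (1.73) and Chac1 (1.23). Lower were Brinp3 (-7.63), Postn (-4.50), Vtcn1 (-3.02), Flt1 (-1.62), Cenpa (-1.09) and mt-Nd3 (-0.81). Acss3, with 2 counts in shEya3_KD1 and 2595 in shEya3_KD2, had a ratio of 1263 (95% counting interval 349 to 10432). Genes with no counts in 1 group were Ccl4, at least 24.3-fold higher in shEya3_KD2, and Cd36 and Ttc12, at least 106-fold and 92.8-fold lower. Single outlying libraries were not tested in groups of 3.

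Of 44 interferon-induced genes 38 fell with shEya3_KD1 and rose with shEya3_KD2. A graded response to the Eya3 level argues for shEya3_KD2 means between those of SCR and shEya3_KD1. Of the 44 members 0 lay there, as the opposite directions already imply for most of them. Of all 8011 genes called with shEya3_KD1, 4410 lay there. Those genes were chosen by the shEya3_KD1 call, and shEya3_KD2 means that differed from SCR only by noise would often lie there too. The 4410 genes therefore give no baseline and do not show a graded response in other genes. A difference in library depth did not account for either direction. With every library thinned to the shallowest total, 44 members still rose in shEya3_KD2. In shEya3_KD1, 38 still fell and 1 rose. Macrophages in the shEya3_KD2 cultures did not account for the rise there. Of 7 tested markers 4 fell and 2 rose (Cd68 and C1qb, by at most 2.43 CPM), with a median log2 fold change of -1.28 over the 7. The 10 markers too low to test stayed at or below 0.0794 CPM, and the interferon list rose by a median of 43.3 CPM. An interferon response to the hairpin itself may still account for the rise in shEya3_KD2, and an unintended target of either hairpin for either direction. Neither was tested. Ifnb1 had 7 counts in SCR, 2 in shEya3_KD1 and 46 in shEya3_KD2.

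Other splits of the libraries were run for the counts of calls. For each comparison of 2 groups 10 splits exist, too few for a share under 0.05. Each split but the real one mixed libraries of both groups, so the difference between the groups entered the spread within each side. Part of that difference also stayed between the sides. These counts of genes and lists therefore give no baseline for unchanged groups. As many genes were called in 1 of 10 splits for shEya3_KD1 against SCR (8011 genes, highest other 0), 1 of 10 for shEya3_KD2 against SCR (7210, highest other 0) and 1 of 10 between the hairpins (7889, highest other 0). As many lists were called in 4 of 10 (7 lists, highest other 9), 7 of 10 (4 lists, highest other 11) and 5 of 10 (5 lists, highest other 8). Of 100 assignments of all 9 libraries to 3 groups 1, the real one, gave as many as 3752 genes called in both. The next gave 3285 and 3065, both with the shEya3_KD1 libraries as the control. Every draw but the real one mixed libraries of different groups, so whole groups with a hairpin group as the control were not drawn. The draws cannot tell whether so many shared calls are particular to SCR as the control.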

How the results depend on the processing

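Thinning to the shallowest library was the only alternative chosen after seeing the data. Eya3 fell under every alternative, with log2 fold changes of -1.71 to -1.61 (shEya3_KD1) and -1.01 to -0.89 (shEya3_KD2) when each library was left out in turn. In the same leave-one-out fits 7044 to 8681 genes changed with shEya3_KD1, 5984 to 7695 with shEya3_KD2, 6747 to 8433 differed between hairpins and 3116 to 3824 changed with both, and camera called 6 to 8, 4 to 6 and 5 lists. With a fold of at least 1.5 (glmTreat), a stricter null by construction, the counts were 2591, 1456, 2087 and 816, of which 36.0%, 40.9%, 60.6% and 26.0% rose, against 47.9%, 50.7%, 54.5% and 43.6% without it. Thinned to the shallowest total they were 7367, 6697, 7433 and 3435. Camera called 0, 0 and 0 lists with an estimated correlation and fry, directional, called 16, 16 and 14. These tests differ in how they treat correlation and in what they ask. Camera compares a list with all other genes, while fry asks only whether the members moved. With 50.3%, 45.3% and 49.6% of genes tested called, a list can pass fry without standing out from other genes. With the replicate number as a replicate block the counts were 8093, 7329, 8017 and 3797; of 9 same-number pairs 3 correlated above 0.1 (range -0.11 to 0.20), as did 3 of 18 pairs of different numbers (-0.24 to 0.17), and 5 of 9 libraries correlated best with their own number, which leaves shared handling of same-numbered libraries undecided. Depth limits genes with few counts, given as bounds or intervals.

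Results whose direction turned (the log2 fold change of a gene, the direction given by camera for a list) had no call in either setting, and the cause was not tested; medians are given for lists. At least 5 CPM in 3 libraries: epithelial genes in shEya3_KD1 -0.39, the Eya-Six-Dach family 0.22 in shEya3_KD2 and 0.27 between hairpins, cell cycle 0.015 and -0.0014, DNA damage between hairpins 0.011. Fry, directional, gave the opposite direction to camera for epithelial genes (-0.052 in shEya3_KD1, -0.064 in shEya3_KD2) and mesenchymal genes between hairpins (0.032). Leave-one-out ranges in shEya3_KD1 were Cd274 -0.073 to 0.033, Frmpd3 -1.76 to 1.93, Hist1h1b -0.71 to 0.022, Sstr5 -0.51 to 0.065 and epithelial genes -0.46 to 0.087. In shEya3_KD2 they were Hist1h2bc -0.076 to 0.19, Tysnd1 -0.071 to 0.043, epithelial genes -0.091 to 0.058 and histones -0.19 to 0.022. Between hairpins they were cell cycle 0.019 to 0.076, epithelial genes -0.029 to 0.31, mesenchymal genes 4.5e-04 to 0.10, collagens and matrix -0.19 to 0.031 and mitochondrially encoded genes -0.12 to 0.096.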

Other observations

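Permuted gene order, DNA copy number, low depth of silent genes, their neighbours and descent were tests chosen only after the result was seen.

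Proliferation and repair genes moved both ways. Of 46 cell cycle genes 11 rose and 9 fell with shEya3_KD1 and 14 rose (6 to 17 with each library left out in turn) and 10 fell with shEya3_KD2. Of 39 Myc targets 6 rose and 9 fell, then 6 rose (3 to 7 with each library left out) and 15 fell; Odc1 fell with both hairpins. Of 33 DNA damage and repair genes 13 rose and 5 fell, then 16 rose and 6 fell, and of 26 p53 targets 6 rose and 9 fell, then 9 rose and 7 fell. Plk2, a polo-like kinase among the p53 targets, had log2 fold changes that differed by 1.73 between the hairpins. Of 23 cholesterol synthesis genes 9 rose and 4 fell, then 11 rose and 4 fell (1 to 4 with each library left out). Of 30 unfolded protein and amino acid stress genes 12 rose and 8 fell with shEya3_KD1. Adjusted over each list alone, 7 and 10 p53 targets rose, 15 cell cycle genes rose with shEya3_KD2, 10 cholesterol synthesis genes rose with shEya3_KD1, 13 stress genes rose and 9 fell, and the other counts of this paragraph stayed the same.

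Matrix and lineage genes also went both ways. Of 25 mesenchymal genes 7 rose and 11 fell with shEya3_KD1 and 6 rose and 11 fell with shEya3_KD2; their median between the hairpins was 0.03 (4.5e-04 to 0.10 with each library left out) and their mean -0.28. Of 31 collagens and matrix genes 11 rose and 9 fell, then 11 rose and 8 fell, with Thbs1 and Bgn higher with both. With shEya3_KD2, 4 of 18 epithelial genes rose and 6 fell, with a median of -0.06 (0.05 with Cldn1 at its bound, -0.091 to 0.058 with each library left out), and 14 of 31 hypoxia and glycolysis genes rose and 3 fell. Of 15 cytokines of myeloid cells 5 rose (1 to 5 with each library left out) and 6 fell, of 28 immediate early genes 11 rose and 6 fell (3 to 6 with each library left out), and of 18 ligands of NK cell receptors and immune checkpoints 5 rose and 8 fell with shEya3_KD2. Adjusted over each list alone, 5 epithelial genes, 15 hypoxia genes and 6 of these ligands rose with shEya3_KD2, 7 cytokines fell, and the other counts of this paragraph stayed the same. Endothelial markers had medians of 0.72 and -0.90 (-0.86 with Emcn at its bound), mitochondrially encoded genes 0.38 (0.24 to 0.53 with each library left out) and 0.25 (0.13 to 0.41), and replication-dependent histones 0.56 (0.22 to 0.56) and 0.03 (-0.19 to 0.026).

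Neighbouring genes shifted together against SCR in 10 blocks of at least 20 genes with shEya3_KD1 and 7 with shEya3_KD2, each the same way in all 3 libraries; 4 of the 10 overlapped one of the 7 in the same direction, and in 8 all 3 shEya3_KD2 libraries moved the same way, by however little. The longest with shEya3_KD1, 300 genes on chromosome 10 (mm10, 74967177 to 128498685), had a median log2 fold change of -0.53, while 66 genes on chromosome 3 (19187327 to 51408988) had -0.49 with shEya3_KD2. For shEya3_KD1, GC content or transcript length bias was argued against, since 97.9% of shifted windows stayed after that trend was removed, and chance order was too, with a largest window median of 0.696 against 0.353 in the permuted orders. A difference in DNA copy number between the cell populations may account for them and cannot be told apart from regulation over a domain, with 92.7% of the genes in the longest block moving its way and no DNA measured. Blocks called with both hairpins may come from the SCR culture instead.

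Some genes on in SCR (above 2 CPM) were at the floor in shEya3_KD1 (below 0.1 CPM): 51 genes, 44 of them protein coding, against 6 in shEya3_KD2. In reverse, 20 genes at the floor in SCR were on in shEya3_KD1 and 6 in shEya3_KD2. Between the hairpins, 31 genes were at the floor in shEya3_KD1 and on in shEya3_KD2, and 20 the other way. Low depth was argued against by the counts themselves. At its SCR level each of the 51 would have had at least 235.7 counts over the shEya3_KD1 libraries, and none had more than 12. SCR libraries thinned to the lowest shEya3_KD1 total held 0 genes at the floor (0% of the 51) among those above 2 CPM in the other SCR libraries. The distance between the 2 CPM and 0.1 CPM bounds largely set that result, so it adds little. Over the 51 genes pooled, loss of large DNA segments was argued against by 408 expressed neighbours with a gap under 500 kb. Of these 0.490% were at the floor, namely 2, Acss3 and Ptprq, which neighbour each other on chromosome 10. Gm47223, Tmtc2 and Syt1, also at the floor, lie on the same stretch (103507362 to 109010982), inside the longest lowered block. The pooled share does not exclude a loss there, or a loss of a single gene elsewhere. Descent of the shEya3_KD1 culture from few cells may account for the 51 genes and cannot be told apart from an effect of the hairpin. They were 45 more than in shEya3_KD2, and no separately derived shEya3_KD1 culture is described in the labels. With shEya3_KD2, 36 of the 51 fell as well (median log2 fold change -1.20 over the 51), while 23 stayed above 2 CPM. The 51 were chosen for being on in the SCR libraries that both comparisons share, and 3554 of all 15914 genes fell with shEya3_KD2.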
